A study of Mus musculus with 6 samples.

How the data were processed

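The series compared mouse embryonic stem cells lacking Mettl5, made by CRISPR/Cas9 editing, with wild-type cells. Per the labels' protocols the cells grew in a serum-free medium with a MEK inhibitor, PD0325901 at 1 µM, a GSK3 inhibitor, CHIR99021 at 3 µM, and leukemia inhibitory factor at 1000 U per ml. They were treated with cycloheximide, which arrests elongating ribosomes, and lysed in polysome buffer. Ribosome-protected fragments (footprints) and input mRNA were taken from the lysates, depleted of ribosomal RNA and made into small-RNA libraries, while the series' design text names a TruSeq ribosome profiling workflow. The labels give the molecule of every sample as polyA RNA and describe it as RiboZero mRNA, so whether the input was selected by poly(A) tails is unclear. Samples were grouped by the genotype and library type in their titles, giving 2 wild-type (WT) and 2 knockout (KO) footprint libraries and 1 input library of each genotype. The labels name no separate cultures, so p-values measure only the spread between these libraries, which may be technical.

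The footprint values were raw read counts per gene, as deposited and named so per the file headers. The authors also gave footprints scaled to the library total (CPM), which equalled the deposited count divided by 1 constant per library, so each library's total before the authors' gene filter was recovered from that constant. The input was deposited by the authors only as CPM. All input values (100% in each library, within a tolerance of 0.01) were whole multiples of the library's lowest value, and the input totals given below hold if that lowest value stands for 1 read. The 2 per-sample columns of a second input library in each genotype held the same values as the first for all 9093 genes and were not used. Translational efficiency (TE) was deposited by the authors as a ratio of footprint CPM to input CPM per footprint library, with the mean ratio of each genotype. The deposited log2 fold of TE was the log2 of the authors' KO mean over their WT mean. The deposited p-value of each gene was unadjusted, and an equal-variance test of the 2 against 2 ratios gave the same values to within 3.74e-13. Because both ratios of a genotype share 1 input library, that test holds no spread of the input. Bowtie and the mm10 build are named per the submitters' processing notes, with no version. The read counter, the annotation and the authors' gene filter are not given in the sources used here.

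The table held 9093 genes, each with at least 11 footprint counts in every library and at least 101 over the 4 libraries. Gene symbols were taken from the table, where 13 had been turned into dates and are named by gene identifier. Positions came from the RefSeq table of the same mouse build (GRCm38, mm10), which matched 9056 genes. Total reads were 3524739 and 8675267 in the WT footprint libraries, 2060010 and 3472613 in the KO footprint libraries, 17912908 in the WT input and 15931259 in the KO input. The median gene had 85 to 367 footprint reads per library and 843 to 908 input reads.

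Footprints were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, library sizes before the authors' filter), 2 KO against 2 WT libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The low-count filter of edgeR removed 0 genes. TE was tested as the interaction of genotype and library type over all 6 libraries. The count model chosen for this before the data were examined was not used because the input was deposited as CPM, and limma 3.58.1 (trend, Benjamini-Hochberg) was fitted to log2(CPM + 1), with a floor of 1 CPM on the mean that also removed 0 genes. TE changes are therefore on the log2(CPM + 1) scale, which understates footprint and input changes of low genes. A TE change, as their difference, can be understated or, where footprints and input both fell, overstated. Both fits had 2 residual degrees of freedom per gene, and in the TE fit all of them came from footprints, so each input library was assumed to vary like a footprint library. Input changes are log2 ratios of single libraries after adding 1 CPM and were not tested. Their 95% intervals cover counting error only, and copied reads are not independent molecules. Intervals in the closing observations came from 1000 bootstrap draws over genes, apart from a binomial interval for chromosome windows. They treat genes or windows as independent and hold no spread between libraries.

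A total of 32 gene lists was fixed before the data were examined, and the 28 with at least 5 measured genes were tested with limma's camera (preset correlation of 0.01, Benjamini-Hochberg over the lists), beside camera with an estimated correlation and fry. Camera compares a list with all other genes, whereas fry asks whether a list's genes move on balance in 1 direction. With an estimated correlation, camera draws on the 2 residual degrees of freedom, so a call lost there need not reflect correlation between genes. For input, a list's median was placed among those of 10000 random lists of the same size and mean expression. The rule for named genes was also fixed in advance. It took Mettl5, Fbxw7 and the 2 further genes Trmt112 and Myc, which were not analysed here. For footprints and for TE it took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean at or above the median, which for footprints also had both KO libraries beyond both WT libraries. For input it took 5 genes per direction under the same level rule, for WT TE the 5 highest and 5 lowest, and for each list up to 4 members with the largest change. A gene that this rule would name is not reported here. Genes of multigene families, such as histones and ribosomal proteins, share reads with near-identical copies and pseudogenes, and their values are uncertain.

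The tests were checked on simulated data drawn from the real means and library sizes over 9093 genes. Of 50 genes changed by 1.25-fold, 1.5-fold, 2-fold and 3-fold, the footprint test called 36%, 78%, 92% and 100%, and 0.112% of unchanged genes. For TE the shares were 0%, 26%, 50% and 82%, with 0% of unchanged genes. Every gene in every simulated library had the same dispersion of 0.001, against a common estimate of 0.000626 for the real footprints. The footprint shares thus hold only if genes vary equally. Both simulated input libraries also shared the same means. The TE shares therefore hold only if real input libraries vary as little as footprint libraries, which the simulation could not check. In each simulation camera called the 1 moved list and 0 of 20 unmoved lists. The simulation was set to stop unless the moved list was called and at most 1 unmoved list was, and its genes were independent. It therefore gives no false call rate for real lists. Alternatives were DESeq2 1.42.0, its size factors in edgeR, stricter filters, other pseudocounts, median centring, a replicate block, ratios per footprint library and leaving out each footprint library. Added after the data were seen were library sizes from the filtered table, leaving out genes on chromosomes 6, 8, 11 and 16, the authors' deposited p-values after Benjamini-Hochberg adjustment, and an extra spread for the input libraries. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.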

Results

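Ribosome profiling and input mRNA sequencing were carried out on mouse embryonic stem cells with and without Mettl5, the enzyme that places N6-methyladenosine on 18S ribosomal RNA, in work whose title concerns stem cell differentiation. Footprints report the position and number of ribosomes on mRNA, and their ratio to input mRNA is the translational efficiency (TE) of a gene. Footprints were measured in 2 WT and 2 KO libraries of 2060010 to 8675267 reads, and input mRNA in 1 library per genotype of 17912908 and 15931259 reads. The cells derive from a cross of 129Sv and C57BL/6 BVSC mice and were held in conditions that keep them in the naive pluripotent state. Footprint libraries of a genotype differed more than sampling alone gives, with a chi-square per degree of freedom of 1.44 for WT and 1.24 for KO, so none was a copy of another. Between genotypes the same value was 7.11 and 13.2.

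The first comparison asked how footprints differed between KO and WT cells, beginning with the targeted gene. Mettl5 (ENSMUSG00000051730.15, chromosome 2, 69871195 to 69886634 in mm10) had 123 and 127 CPM of footprints in the WT libraries and 9.71 and 11.2 CPM in the KO libraries. Its footprints fell 11.6-fold (log2 change of -3.53 ± 0.14 SE, edgeR adjusted p = 2.23e-130). Input mRNA of Mettl5 was 25.8 CPM in WT and 6.47 CPM in KO, a log2 ratio of -1.84 with a 95% counting interval of -2.15 to -1.54. Fbxw7 (ENSMUSG00000028086.15, chromosome 3, 84814990 to 84979198), the substrate receptor of a ubiquitin ligase that targets Myc and cyclin E, fell from 26.5 ± 1.79 to 15.5 ± 2.06 CPM of footprints (mean ± SD, n = 2 per genotype). That is a log2 change of -0.74 ± 0.19 (edgeR adjusted p = 0.000609), while the input ratio of Fbxw7 was 0.22 (0.01 to 0.43). With DESeq2 the footprint change of Fbxw7 missed the threshold (adjusted p = 0.0572, and 0.000588 to 0.0572 over all settings tried).

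**Figure D1:**
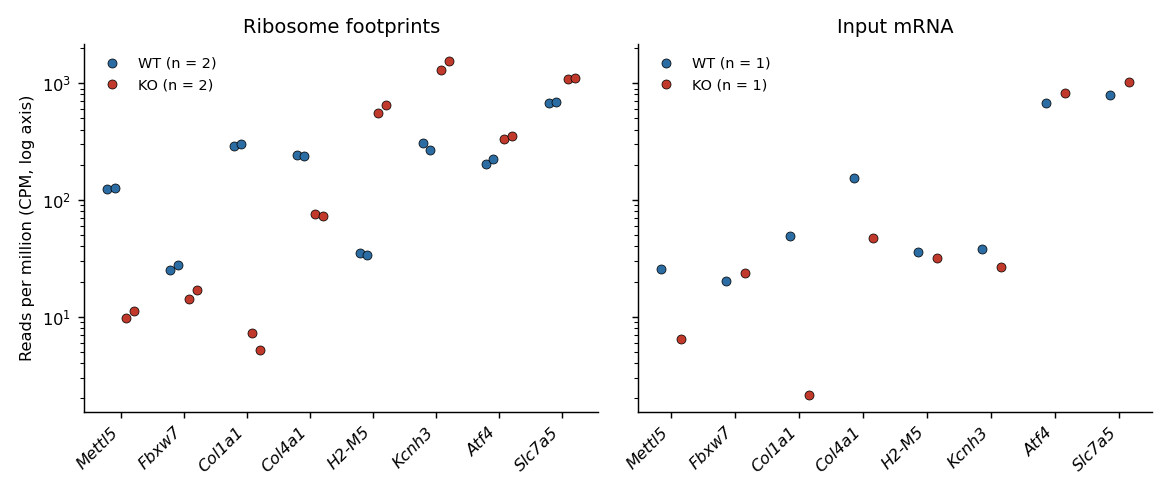
Scaled read counts (CPM, log axis) of 8 genes in each library, with footprints on the left (2 libraries per genotype) and input mRNA on the right (1 per genotype), and each point a library. Mettl5 footprints lie at 123 and 127 CPM in WT and at 9.71 and 11.2 CPM in KO, and H2-M5 and Kcnh3 are higher in KO footprints but not in KO input.

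Outside the targeted gene, the largest fall was that of Col1a1, a chain of type I collagen made by fibroblasts, from 296 ± 5.25 to 6.23 ± 1.48 CPM (log2 change of -5.61 ± 0.13, edgeR adjusted p = 0, below what the software can represent). The basement membrane genes Lamb1, a laminin chain, and Col4a1, a type IV collagen chain, fell as well, at -1.70 ± 0.06 and -1.67 ± 0.08. Plekhg1 fell by 2.21, Klhl22, a substrate adaptor of cullin 3, by 2.07, Fstl1, a secreted glycoprotein, by 1.80, and Grb10, an imprinted adaptor of insulin signalling, by 1.78 on the log2 scale. The secreted protease gene Htra1 and the germ cell gene Tex19.1 both fell by 1.70. The largest rises were those of H2-M5, a nonclassical MHC class I gene, from 34.2 ± 0.956 to 602 ± 62.4 CPM (18.2-fold), and Kcnh3, a voltage-gated potassium channel, from 286 ± 27.1 to 1430 ± 179 CPM (5.22-fold). H2-M5 belongs to a multigene family, so its reads are uncertain. Arhgap45, a GTPase-activating protein, rose by 1.41 ± 0.09, the LIM-domain gene Crip1 by 1.33 ± 0.06, the fatty acid-binding protein gene Fabp5 by 1.17 ± 0.12 and Bst2, the antiviral protein tetherin, by 1.13 ± 0.06 on the log2 scale. Hist1h4j rose by 1.21 ± 0.11, Slc11a1, a metal ion transporter, by 1.11, and Sft2d2 and Tagln2 each by 1.08.

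Over 9093 genes, edgeR with Benjamini-Hochberg adjustment called 1668 genes higher and 1458 lower in KO footprints. Of these, 496 and 444 were past 1.5-fold and 71 and 107 past 2-fold. The libraries of a genotype were close to each other (biological coefficient of variation of 2.5%), so small changes passed the test. DESeq2 called 772 higher and 636 lower, and without the second KO library edgeR called 1015 higher and 920 lower.

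Genes that changed were not spread evenly over the genome. On chromosome 8 the median log2 footprint change was 0.39, and 338 of 522 genes rose while 12 fell, and on chromosome 6 the median was 0.31, with 213 of 417 genes rising and 22 falling. On chromosome 11 the median was -0.19, with 275 of 772 genes falling and 44 rising, and on chromosome 16 it was -0.25, with 125 of 284 falling and 6 rising. Medians of the other chromosomes lay within 0.05 of 0. A permutation test of chromosome labels gave p = 1e-04 for each of these 4 chromosomes, the smallest that 10000 permutations can give, and 95% of permutations had a largest median under 0.0604. Input mRNA had medians of 0.31, 0.35, -0.24 and -0.13 on chromosomes 8, 6, 11 and 16. Among the genes named above, Bst2 lies on chromosome 8, Col1a1, Grb10 and Tex19.1 on chromosome 11, and Klhl22 and Fstl1 on chromosome 16, whereas Col4a1 fell although it lies on chromosome 8. Without these 4 chromosomes, 1018 genes were higher and 985 lower among 7098.

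**Figure D2:**
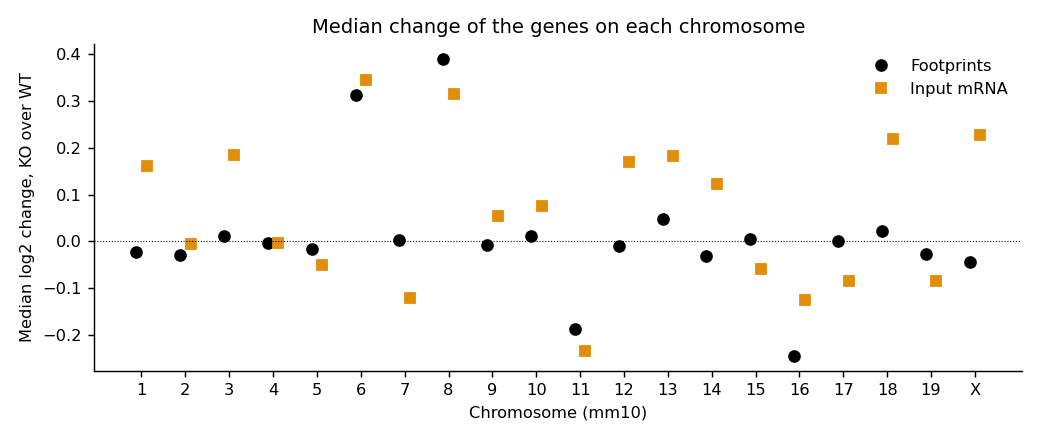
Median log2 change (KO over WT) of the genes on each chromosome, for footprints (circles, 2 libraries per genotype) and input mRNA (squares, 1 per genotype). Footprint medians are 0.39 and 0.31 on chromosomes 8 and 6 and -0.19 and -0.25 on chromosomes 11 and 16, and lie within 0.05 of 0 elsewhere, while input medians vary more.

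Genes of the integrated stress response, the programme run by the transcription factor Atf4, rose as a group, with 17 of 24 members higher, 2 lower and 5 not passing the test. Atf4 itself rose from 214 ± 14.0 to 343 ± 14.0 CPM (log2 change of 0.69 ± 0.05), the amino acid transporter Slc7a5 by 0.71 ± 0.04, the stress protein gene Nupr1 by 0.71 ± 0.08 and the stress transcription factor Atf3 by 1.29 ± 0.22. Slc7a5 lies on chromosome 8. Replication-dependent histone genes also rose, 35 of 54 being higher, 5 lower and 14 neither, and Hist1h4k rose by 0.99 ± 0.04 and Hist1h4f by 0.71 ± 0.05. Histone genes share near-identical sequences, so reads may be split between them. The counts of both lists were the same adjusted over the list alone. Camera adjusted p-values over 28 lists were 1.18e-10 for the stress response (median log2 change of 0.44) and 2.31e-10 for histones (0.29). Both calls were lost with an estimated correlation (camera adjusted p = 0.471 and 0.381). Camera then had only 2 residual degrees of freedom, and the histone call was lost although its estimated correlation was -0.0077. The estimate for the stress response was 0.144, above the preset 0.01, so its preset p-value may be too small.

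Markers of endoderm fell, with 5 of 5 measured members lower, 0 higher and a median of -1.54. These were Lamb1, Col4a1, Col4a2 (-1.54 ± 0.08), Lama1 (-0.72 ± 0.05) and Sparc (-0.49 ± 0.03, on chromosome 11), which encode basement membrane proteins, while the endoderm transcription factors were not analysed here. Of 6 measured genes of fibroblasts, which often serve as feeder cells, 5 fell and 1 rose, with a median of -1.16. Besides Col1a1, the matrix genes Col5a1 (-1.99 ± 0.19) and Fbln2 (-1.62 ± 0.22) fell, but the fibronectin gene Fn1 rose slightly, from 2760 to 3087 CPM. Among 9 formative and primed pluripotency genes 5 fell, 1 rose and 3 passed in neither direction. These included Dnmt3b, a de novo DNA methyltransferase, at -1.49 ± 0.14, Foxd3 at -1.06 ± 0.20 and Zic2 at -0.82 ± 0.11. The counts of these 3 lists were the same adjusted over the list alone. Camera adjusted p-values were 2.28e-17, 4.28e-05 and 0.0139 for endoderm, fibroblast and formative genes, against an adjusted p = 0.381, 0.471 and 0.471 with an estimated correlation. In the latter form camera had only 2 residual degrees of freedom. Estimated correlations were 0.332, 0.317 and 0.085 for the 3 lists, above the preset 0.01, so the preset p-values may be too small. The formative call was also lost without the second WT library (adjusted p = 0.0727) and without the first KO library (adjusted p = 0.0564).

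Naive pluripotency genes moved both ways, with 8 of 22 higher, 6 lower and 8 neither, and 8 and 7 adjusted over the list alone. Dppa3 and Klf4 rose by 0.49 and 0.47, whereas Nr0b1, which encodes an orphan nuclear receptor, fell by 1.11 on the log2 scale. Dppa3 and Nanog (0.34) lie on chromosome 6, and Klf2 and Zfp42 (0.33 each) on chromosome 8. Footprint medians of all genes on these chromosomes were 0.31 and 0.39. No list was tested without the chromosomes that shifted as a whole, so those shifts may add to the counts. Of small ribosomal subunit genes, 8 of 20 rose and 3 fell (10 and 3 adjusted over the list alone), with Rps26 at 0.59 and Rps7 at 0.56, and the camera adjusted p was 0.0501. Large subunit genes had 3 of 21 higher and 4 lower (4 and 5 adjusted over the list alone), and mitochondrial ribosome genes had 9 of 73 higher and 17 lower (10 and 17). Translation initiation factors had 8 of 35 higher and 9 lower (8 and 10), and elongation and release factors had 6 of 15 higher and 2 lower (6 and 2). Among genes of ribosomal and transfer RNA modification, 3 of 15 rose and Mettl5 alone fell. For proteasome genes 6 of 31 rose and 12 fell (7 and 14), for Myc targets 3 of 24 rose and 6 fell (3 and 6), and for Fbxw7 substrates 3 of 15 rose and 4 fell (4 and 5). None of these lists was called by camera in footprints, where the smallest adjusted p among them was that of the small subunit. The median, the mean and the camera direction differed in sign for RNA modification genes, naive pluripotency, large subunit genes, initiation factors, glycolysis, DNA replication and germ cell genes.

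Input mRNA was compared between 1 library of each genotype, so differences have no replicate check. The desmosome gene Dsp was higher in the KO library, at 325 against 79.0 CPM (log2 ratio of 2.03, 1.94 to 2.11), as were the cohesin gene Smc1a (1.54), Exoc6b (1.49), Mkln1 (1.48) and Mob1a (1.48). The last 3 lie on chromosome 6. The protease gene Htra1 was lower in the KO library (-2.13, -2.29 to -1.97), as were Dusp27 (-1.84), Klhl22 (-1.83) and the collagen genes Col4a2 (-1.81) and Col18a1 (-1.78). Over all genes the log2 ratio had a median of 0.05, a standard deviation of 0.48 and a 10th to 90th percentile range of -0.48 to 0.71. Medians of the endoderm (-1.71), fibroblast (-1.16), formative (-0.54) and mitochondrial ribosome (-0.18) lists lay at percentiles 0.00, 0.00, 0.02 and 0.05 of random lists matched on expression. The mitochondrially encoded genes (0.46) and the stress response genes (0.20) lay at percentiles 99.5 and 97.7. Random lists were not matched on the number of nearby genes, with which the input ratio also fell, as given below. The tenth of genes with the most neighbours had a median of -0.19, so the mitochondrial ribosome percentile may reflect that trend. Across genes, footprint and input changes correlated with a Pearson r of 0.523 and a Spearman rho of 0.464, although genes are not independent replicates.

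The second comparison asked which genes changed in TE, the footprint change beyond that of input mRNA. Among genes at or above the median level, Sucla2, a subunit of mitochondrial succinyl-CoA synthetase, fell most, by 1.49 (± 0.12 SE, limma adjusted p = 4.58e-09), with footprints down from 378 ± 10.6 to 195 ± 6.21 CPM and input at 39.9 CPM in WT and 58.6 CPM in KO. The next 9 falls at that level all came with higher KO input, and footprints of Golgb1, Dnajc13 and Kif14 fell while those of the rest, apart from a slight rise of Hsp90aa1, passed in neither direction. Smc1a fell by 1.39 in TE, with 155 ± 7.86 and 172 ± 9.09 CPM of footprints in WT and KO but 30.5 and 90.5 CPM of input, and Hsp90aa1, the inducible form of the chaperone Hsp90, fell by 1.31 (± 0.06) with 1107 ± 33.5 and 1161 ± 8.85 CPM of footprints but 207 and 541 CPM of input. TE also fell for the microtubule-end protein gene Clip1 (-1.43), the Golgi gene Golgb1 (-1.40), the helicase gene Ddx10 (-1.39), the mitotic kinesin gene Kif14 (-1.36), the histone demethylase gene Kdm5a (-1.36) and, at -1.39 and -1.36, for Dnajc13 and Usp47. Rises were led by H2-M5 at 4.27 ± 0.16 and Kcnh3 at 2.81 ± 0.13 (limma adjusted p = 5.1e-14 and 8e-13), whose input log2 ratios were -0.18 and -0.50. TE of Eef1g rose by 1.28 ± 0.20, of Hist1h4j by 1.28 ± 0.15, of the histone variant gene H2afx by 1.07 ± 0.08 and of the splicing factor gene Snrpd2 by 0.91 ± 0.20. Smaller rises were those of Hist1h4k (0.84), Pcnx3 (0.81), Ppp1r35 (0.81) and Rpl41 (0.77), and the histone, Eef1g and Rpl41 values are uncertain because of gene copies.

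Below that level, TE of Col1a1 fell by 1.38 (± 0.29, limma adjusted p = 0.00148) although its KO input was lower, at 2.13 against 49.1 CPM. The added 1 CPM overstates this fall, because it shrinks the input ratio more than the footprint change (TE change of -1.11 with 0.1 CPM added). TE of Mettl5 fell by 1.62 (± 0.28, limma adjusted p = 0.000229) and that of Fbxw7 by 0.96 (± 0.31, limma adjusted p = 0.0371). The Mettl5 call missed the threshold with the authors' deposited p-values after Benjamini-Hochberg adjustment (adjusted p = 0.0508) and with an added spread for the input libraries (0.243, within a range of 1.19e-09 to 0.243 over all settings). The Fbxw7 call was lost with median centring (adjusted p = 0.0605), without the first WT library (0.0909) and without the second (0.153), within a range of 0.00264 to 0.508 over all settings. The Fbxw7 call was also lost with the authors' p-values after Benjamini-Hochberg adjustment (adjusted p = 0.091). With limma and the added input spread it was lost too (adjusted p = 0.508). In the authors' deposited table the mean TE was 4.86 in WT and 1.62 in KO for Mettl5 and 1.31 and 0.655 for Fbxw7, with unadjusted p-values of 0.00182 and 0.0173.

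In all, limma called TE of 444 genes higher and 1165 lower, 76 and 839 of them past 1.5-fold and 13 and 186 past 2-fold. Centring each library on its median turned the split into 756 higher and 883 lower (46.1% against 27.6% higher). Higher calls numbered 279 without the first WT library, 696 without the first KO library and 811 without the second. The genes with lower TE had a median footprint change of -0.07 and a median input ratio of 0.66. Since a TE change is the footprint change less the input ratio, choosing genes by a TE call favours input ratios of the opposite sign by construction. Among the genes with lower TE 308 genes fell in footprints, 198 rose and 659 passed in neither direction. Genes with higher TE had a median footprint change of 0.15 and a median input ratio of -0.30, and 219 of 444 rose in footprints, 58 fell and 167 did neither. Independent lists would share 187 lower and 81.4 higher genes, but both tests use the same footprint libraries, so the excess is no measure of a shared effect. The authors' deposited table marks 1169 genes as lower and 170 as higher, of which 833 and 75 were called the same way here. These counts rest on the assumption that single input libraries vary as little as footprint libraries. With an added spread of 0.2 (log2) per input library, limma called 4 higher and 0 lower (46 and 696 at an unadjusted p under 0.05), H2-M5 and Kcnh3 being the only genes named above among them, and the authors' deposited table gave 36 higher and 107 lower genes after Benjamini-Hochberg adjustment.

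**Figure D3:**
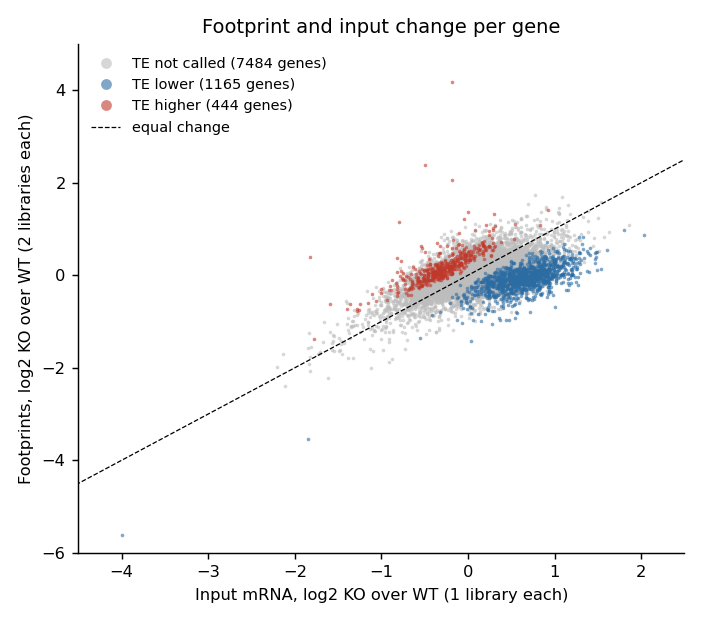
Footprint change against input change (log2, KO over WT) for each of 9093 genes, coloured by whether TE was called lower (1165 genes), higher (444) or not, with a dashed line of equal change. Genes with lower TE lie to the right of the line, at a median input ratio of 0.66 and a median footprint change of -0.07.

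Of the gene lists, replication-dependent histones stood out in TE, with 31 of 54 higher, 0 lower and 23 neither (35 and 0 adjusted over the list alone). These mRNAs mostly lack poly(A) tails, and the labels leave open whether the input was selected by them, so the level of histone TE depends on how the input was made. Hist1h3d rose by 0.74 and Hist1h2ak by 0.62 on the log2 scale. Stress response genes had 9 of 24 higher and 0 lower (11 and 0), with the transcription factor Cebpb at 0.99, a call lost without the first WT library (adjusted p = 0.153), and the amino acid transporter subunit Slc3a2 at 0.47. Of naive pluripotency genes 5 of 22 rose and 2 fell (6 and 2), and Utf1 (0.76) and Klf2 (0.58) rose while Tfcp2l1 fell (-0.64). Glycolysis had 5 of 17 higher and 0 lower (6 and 0), such as Tpi1, on chromosome 6, and Pkm, both at 0.33. Small ribosomal subunit genes had 3 of 20 higher and 1 lower (4 and 1), Fbxw7 substrates 2 of 15 higher, Klf2 and Notch1 (0.56), and 1 lower (3 and 1), and nuclear-encoded oxidative phosphorylation 8 of 67 higher and 5 lower (8 and 5), the largest being the fall of Ndufa1 (-0.77). Lower were the mitochondrially encoded genes, with 3 of 7 lower (4 adjusted over the list alone), mt-Co1 at -1.22, mt-Cytb at -0.57 and mt-Nd6 at -0.53. Mitotic genes of the G2 and M phases had 9 of 24 lower and 0 higher (9 and 0), among them the kinesins Kif11 (-1.11) and Kif23 (-1.08), the topoisomerase Top2a (-1.10) and the kinetochore motor Cenpe (-1.01).

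Camera adjusted p-values were 9.02e-21 for histones, 0.00031 for the stress response, 0.00127 for mitochondrially encoded genes, 0.0171 for glycolysis, oxidative phosphorylation, Fbxw7 substrates and mitosis, 0.0209 for naive pluripotency and 0.021 for the small subunit. All 9 calls were lost with an estimated correlation, at an adjusted p = 0.415 or above. This included naive pluripotency, the small subunit and glycolysis, whose estimated correlations (-0.021, -0.024 and -0.044) lay under the preset 0.01. The estimates for mitosis (0.252), mitochondrially encoded genes (0.0938), the stress response (0.0506), Fbxw7 substrates (0.0437) and histones (0.023) lay above it. Their preset p-values may therefore be too small. With 2 residual degrees of freedom, the loss cannot show whether correlation between genes produced the calls. The mitotic call was lost with median centring (adjusted p = 0.0502), and the small subunit and oxidative phosphorylation calls without the second KO library (0.081 and 0.0569). Fry lost all 9 calls as well (fry adjusted p = 0.055 to 0.27). Each list's TE change rests on 1 input library per genotype, so an input bias shared by its genes would not enter the list p-values. No input spread was added in the list tests. Lists not called in TE held strong single changes too. TE of Ncl (-1.05) and Tfrc (-1.07) fell among Myc targets (4 of 24 higher, 7 lower), Pola1 (-1.12) and Rfc1 (-1.10) among DNA replication genes (4 of 28 higher, 4 lower), Eif3a (-0.93) and Eif3e (-0.92) among initiation factors (7 of 35 higher, 9 lower) and Rpl32 (-1.08) among large subunit genes (4 of 21 higher, 2 lower). Of these and the mitotic genes, Rpl32 lies on chromosome 6, Tfrc on chromosome 16 and Top2a on chromosome 11. RNA modification genes had 0 of 15 higher and 3 lower by limma, namely Mettl5, Dkc1 (-0.93) and Nop58 (-0.84). The camera direction differed in sign from the median or the mean for RNA modification, fibroblast, germ cell, Myc target, large subunit, elongation factor, p53, cholesterol and DNA replication genes.

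**Figure D4:**
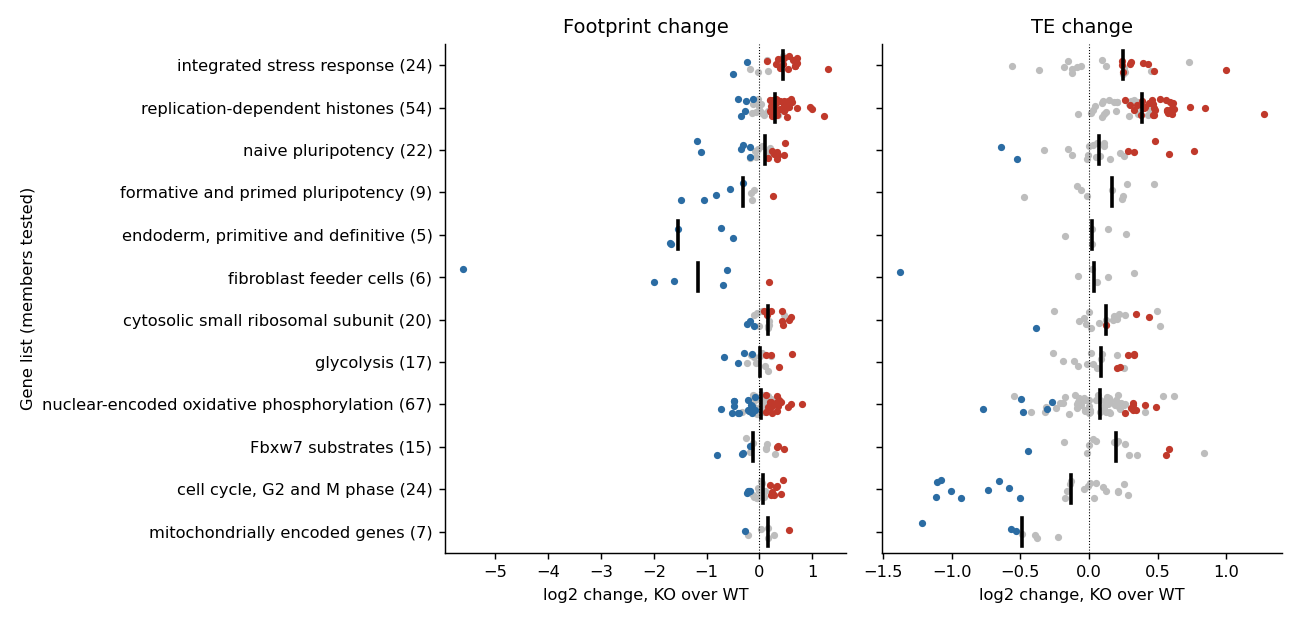
Log2 change (KO over WT) of the members of 12 gene lists in footprints (left) and TE (right), with red and blue points for members called higher and lower, grey points for others and a black bar at the median. All 5 measured endoderm markers are lower in footprints, and 31 of 54 histone genes are higher in TE.

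Finally, TE was set side by side across genes within each genotype. TE ranked genes alike in both genotypes (Spearman rho of 0.934 across genes, which are not independent replicates). The 10th to 90th percentile range was 0.325 to 2.88 around a median of 0.893 in WT and 0.334 to 2.26 around 0.857 in KO, and the standard deviation of log2 TE was 1.27 and 1.15. In WT the highest values of log2 TE were those of Hist3h2a (7.16), Usmg5 (6.82), Hypk (5.80), Hist1h2ad (4.67) and Esf1 (4.30), of which Hist3h2a, Usmg5, Hypk and Esf1 had under 10 CPM of input, so that the added 1 CPM lowers their values (7.75 for Hist3h2a with 0.1 CPM added). Hist3h2a and Hist1h2ad are histone genes with the same uncertainty of the input. The lowest were those of the mitochondrial gene mt-Nd1 (-5.02), which is read by mitochondrial ribosomes, the ADP/ATP carrier gene Slc25a5 (-4.44), Hist1h2bb (-4.03), Hist1h3e (-3.97) and Rnf10 (-3.61).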

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

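Leaving out chromosomes 6, 8, 11 and 16, library sizes from the filtered table, the authors' deposited p-values and the added input spread were settings chosen only after the data were seen. No gene was called in opposite directions under any setting tried. Of 115 named footprint changes, 96 kept their call in every setting in which they were tested. The other 19 lost it in at least 1 setting, all 19 with DESeq2. Some changes were not tested in every setting, for want of an adjusted p-value or because the setting left the gene out. Of 84 named TE changes, 82 lost their call with the added input spread and 71 with the authors' p-values after adjustment, and 0 of the 84 kept it in every setting, since H2-M5 and Kcnh3 missed the threshold with the authors' p-values. Footprint counts of 1668 higher and 1458 lower genes were 1666 and 1460 with DESeq2's size factors, 1593 and 1377 with a mean of at least 50 counts, and the same with library sizes from the filtered table. They were 772 and 636 with DESeq2, for which 706 adjusted p-values were missing, 1018 higher without the 4 chromosomes, where fewer genes were tested, and ranged from 1015 to 1480 and from 920 to 1253 on leaving out 1 library, lowest without the second KO library. TE counts of 444 and 1165 became 756 higher with median centring, 850 and 2115 with ratios per footprint library, 36 and 107 with the authors' adjusted p-values and 4 and 0 with limma and the added input spread (46 and 696 at an unadjusted p under 0.05). On leaving out 1 library they ranged from 279 to 811 and from 823 to 1589, with 279 higher without the first WT library, 696 without the first KO library and 811 without the second. Mettl5 TE lost its call with the authors' values (-1.58, adjusted p = 0.0508) and with the added spread, which widens the error but leaves the estimate of -1.62 as it was (adjusted p = 0.243), against adjusted p-values down to 1.19e-09 elsewhere. The standard deviation of the input ratio moved from 0.476 to 0.499 with a pseudocount of 0.1 and to 0.419 with 5, and the rank correlation of TE ranged from 0.923 to 0.934 on leaving out a library (0.923 without the second KO library, 0.927 without the second WT library). Of 10 named values of log2 TE in WT, 5 moved with a pseudocount of 0.1, the largest move being that of Hist3h2a from 7.16 to 7.75, and 21 of 132 named input ratios and 3 of 28 input list medians moved under at least 1 other scaling or pseudocount. Camera's 2 higher and 3 lower footprint lists became 0 and 0 with an estimated correlation (1 and 1 at an unadjusted p under 0.05) and 7 and 8 with fry. On leaving out a library they stayed at 2 to 3 and 2 to 3. Camera's 7 higher and 2 lower TE lists became 0 and 0 with an estimated correlation (1 and 0 unadjusted), 0 and 0 with fry (7 and 7 unadjusted), 1 lower with median centring, and 5 to 7 higher and 3 lower on leaving out a library. A replicate block gave 1580 and 1372 footprint genes and 441 and 1200 TE genes, and deviations of libraries with the same number correlated at -0.03 across genes. That gives no sign of pairing by number, but deviations this close to sampling error could hide a pairing. The cause of these differences was not tested unless stated. Count tests of TE were not run because the input was given as CPM, and leaving out the low-value filters changes nothing because they removed 0 genes. The shallowest library, the first KO footprint library with 2060010 reads and a median of 85 per gene, limits what small changes can be seen, as does the single input library of each genotype for TE.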

Other observations

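The tests of mRNA abundance and of base composition on chromosomes 6 and 8 were chosen only after the result was seen, as were Extl3 and Ddit4l. Further gene lists held single changes in footprints that their counts do not convey, all from edgeR with Benjamini-Hochberg adjustment. Among 11 imprinted genes 6 fell and 3 rose (6 and 4 adjusted over the list alone), with Grb10 at -1.78 and Plagl1, a zinc finger factor, at -1.22. Of 7 germ cell genes 3 rose and 3 fell, and Prdm1, which encodes Blimp1, rose by 1.00 ± 0.08, from 80.9 ± 6.34 to 159 ± 15.7 CPM, while the RNA-binding protein gene Dazl fell by 1.22 ± 0.10. Of 5 neuroectoderm genes 3 rose and 1 fell, with Nes, an intermediate filament gene, at 0.83 ± 0.09 and Ncam1 at 0.61 ± 0.06, but Olig2, at 12.6 CPM in WT and on chromosome 16, at -1.24 ± 0.28. None of these 3 lists was called by camera (adjusted p = 0.408, 0.964 and 0.104).

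Among 18 p53 targets 7 fell and 3 rose (7 and 3 adjusted over the list alone), with Trp53inp1 at -0.88 and Ccng1 at -0.85 against Pmaip1 at 0.89 and Gdf15 at 0.79, and the camera adjusted p was 0.104. Of 5 measured Wnt pathway genes 3 fell and 0 rose, led by the Wnt deacylase gene Notum, on chromosome 11, at -1.36 (camera adjusted p = 0.104). Of 4 ERK feedback genes Etv5, on chromosome 16, fell, at -1.10, and the other 3 passed in neither direction. Of 12 LIF and STAT3 targets 4 rose and 5 fell, with Junb, on chromosome 8, at 0.63. Of 21 cholesterol synthesis genes 2 rose and 5 fell (3 and 8 adjusted over the list alone). Oxidative phosphorylation had 20 of 67 genes higher and 16 lower, glycolysis 4 of 17 and 4, mitosis 8 of 24 and 4, DNA replication 6 of 28 and 6, mitochondrially encoded genes 1 of 7 and 1, and mRNAs under translational repression or with upstream reading frames 3 of 14 and 2, and camera called none of them in footprints. Of the lists too small to test, trophectoderm had 2 of 4 genes higher, while the 3 measured mesoderm genes and the 1 measured gene of the 2-cell-like state, Eif1a, passed in neither direction. With the added input spread, the 4 genes still called higher in TE by limma were H2-M5, Kcnh3, Extl3 (2.22) and Ddit4l (2.18).

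Over all genes the input ratio, from 1 library per genotype, had a standard deviation of 0.476 against 0.386 for the footprint change, and it enters each TE change with its sign turned. Across 9056 genes the input ratio fell with the number of genes within 500000 bases, a stand-in for base composition (Spearman rho of -0.39), while the footprint change did not follow it (0.0034), a difference in size of 0.386 (0.353 to 0.401), consistent with a composition or library bias of the input as a candidate explanation. A change of mRNA abundance with footprints held level remains open too: WT footprints correlated better with the KO input than with the WT input, by 0.0299 (0.0254 to 0.0339) or more in Pearson r. By the bound set for that test, this result in both WT libraries counted against the explanation. The bound was too strict, however, because footprints of both genotypes lay nearer the KO input (r of 0.699 with WT input and 0.760 with KO input for the first KO footprint library). A true change of mRNA toward footprint levels would share that. With 1 input library per genotype these explanations cannot be told apart, and both may act. The TE change rose with the number of nearby genes (Spearman rho of 0.437 across genes). Whether this trend carries the TE list calls or the input percentiles of lists was not tested.

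Genes on chromosomes 6 and 8 were higher in KO footprints and input. The density trend of the input does not carry this, since the input medians exceeded those of genes of the same local density on the other autosomes by 0.323 (0.281 to 0.350) or more. All 15 windows of 20 megabases along both chromosomes (100%, 78.2 to 100) had a footprint median above that of all genes, from 0.08 to 0.51, against 51 of 103 windows on 15 other autosomes. Both chromosomes were picked from these same footprints, with 82.3% and 89.3% of their genes above 0, so windows above were likely beforehand. Neighbouring windows are not independent either, so the interval is too narrow. A gain of both chromosomes in part of the KO cells is a candidate explanation, as 3 copies in place of 2 in every cell would give 0.58 on the log2 scale, and gains of chromosome 8 are common in cultured mouse embryonic stem cells. All 12 windows on chromosomes 11 and 16, picked in the same way, lay below, from -0.30 to -0.12. That might equally reflect extra copies in the WT cells, and no DNA was analysed here.

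The 5 measured genes of the endoderm list, and the 6 of the fibroblast list apart from Fn1, which rose (0.18, input ratio 0.11), fell in KO footprints, with a median TE change of 0.02 for the endoderm list. Loss of fibroblast feeder cells that were present only with the WT cells may account for Col1a1: among 11 abundant fibroblast transcripts, of which Ctgf is also in the fibroblast list, 7 fell, including Vim (-1.46, from 358 CPM in WT), 1 rose and 3 did neither, with a median of -0.62 (-1.09 to -0.05), or -0.59 without Ctgf. Against this, Lgals1 (-0.05, 334 CPM in WT) and Tpm1 (-0.01) did not pass the test and Cnn2 rose (0.54). All 11 genes also had footprints in KO cells, which could hide a small share of feeder RNA. Every gene in the table had at least 11 counts in each library, however, so a gene silent in KO cells could not be seen. Of 19 abundant fibroblast transcripts chosen, 8 were not analysed here. Fewer endoderm-like cells among the KO cells would lower further basement membrane and endoderm markers, of which 8 of 13 fell, 2 rose and 3 did neither, with a median of -0.15 (-0.36 to -0.04). Of the 22 such markers chosen, 9 were not analysed here, with the same limit. The fibroblast spread crosses both bounds set for these tests (-0.5 if such cells were the source, -0.2 if not), and the endoderm spread lies above -0.5 but crosses -0.2, so neither source is excluded, and a change within the stem cells themselves was not tested.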
